A study of Mus musculus with 10 samples.

How the data were processed

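The data were HTSeq counts of 10 poly(A)-selected RNA-seq libraries from mouse left atria, made with a directional kit per the labels' protocols. The deposited values were raw counts of reads per gene, one file per library, with no normalization. Per the submitters' processing notes, STAR, HTSeq and edgeR were used and the genome build was mm9; the versions, annotation and filters are not given in the sources used here. Per the names of the deposited files the counting ignored strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads of near-identical copies, such as pseudogenes and members of the MHC family, can be split or lost.

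Each file held 37583 gene rows and 5 rows for unassigned reads, which stayed out of the library sizes and tests. Reads in no feature made up 13.5% to 19.9% of the counted records, reads without a unique position 11.8% to 27.4% and ambiguous reads 3.14% to 3.99%. The deposited gene identifiers were Ensembl identifiers, of which 32860 (87.4%) were matched to symbols. The gene annotation used here for gene types and gene order was GENCODE vM21, which is of another build than mm9, so no coordinates are printed. The files held no mitochondrially encoded genes. Total counts on genes per library ran from 14907331 to 19960947, so that 3 counts in a library correspond to 0.15 to 0.201 CPM.

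Groups came from the sample titles, and the number in a title names the library. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 15364 genes holding at least 99.77% of each library's gene counts. Libraries were scaled by trimmed mean of M values (TMM), with factors from 0.87 to 1.026 in CTL, IBR and WT and of 1.157 and 1.228 in KO26 and KO337. All libraries entered a single quasi-likelihood fit with a mean per group and robust shrinkage, which left 6 residual degrees of freedom. The common biological coefficient of variation was 0.221, and 0.168 and 0.294 in the CTL with IBR and the WT with KO libraries alone, so the shared spread lies below that of the genotype libraries. The contrasts were IBR minus CTL, KO minus WT and the difference of both. P-values were adjusted by Benjamini-Hochberg, and "called" means an adjusted p under 0.05. CPM values are TMM-scaled. A standard error is the log2 fold change over the square root of its F statistic.

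Before the data were examined, 42 gene lists were written (cardiac functions, metabolism, stress, signalling, inflammation, and markers of cell types an atrium could hold), with 714 genes, of which 689 were found in the files and 638 tested. Lists with 4 or more tested members, 38 in all, were tested by camera with a preset inter-gene correlation of 0.01, by camera with an estimated correlation and by fry; the sex-linked genes were left out, and showed high Ddx3y (107 to 242 CPM) and low Xist (at most 2.31 CPM) in every library. A call of a list by the preset correlation assumes that its members vary almost independently between libraries. The correlation of both effects was tested by recomputing it for all 120 assignments of libraries to groups within each experiment.

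Genes named in the text were chosen by a rule fixed before the data were examined. It takes 14 genes always reported (Csk, Btk, Nppa, Nppb, Myl7, Myl2, Col1a1, Col3a1, Postn, Acta2, Lyz2, Il6, Kcna5 and Gja5), then, per direction, the 8 called genes with the largest fold change among those with an average log2 CPM of 1 or more, a symbol that is not a clone or Gm number, and groups that do not overlap, filled by the smallest p, and lastly the 3 members with the smallest p in each called list. For the difference of effects it takes 5 per direction. Of the list members, those not called are given in the text for 1 or 2 members per list, and all others stand in the tables. Members of lists that were not called are named where their own adjusted p passed. A few genes that the rule takes are not reported here, and they stay in all counts and tests.

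The calls of genes for both comparisons, camera for 1 shifted list and the correlation of effects were tested on simulated counts. These had each gene's mean over all 10 libraries, the real library sizes and the dispersions of the shared fit. For the calls, 200 genes were changed per comparison. Real differences between the experiments were thus absent. The shared spread (0.221) lay below that of the WT and KO libraries alone (0.294), so the results for KO against WT can be too favourable. Of 100 genes changed 2-fold, 68 were recovered for IBR against CTL and 24 for KO against WT, and of 100 changed 4-fold, 94 and 85 were recovered, with 12 and 8 false calls among 14964 genes. A 2-fold shift of the interferon list in simulated IBR libraries was called with the preset correlation (adjusted p = 1.13e-34) and with the estimated correlation (adjusted p = 0.000975). The simulated genes varied independently of each other, whereas the estimated correlation of this list in the real data was 0.633. The simulation therefore does not show that either list test would behave alike on the real libraries.

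Alternatives covered scaling (relative log expression and upper-quartile factors), filters (none, or a mean of at least 5 CPM), tests (DESeq2 1.42.0, limma-voom, no robust shrinkage), only the libraries of a comparison, thresholds of 0.1 and 0.01, the replicate number as a block, other list tests, and each library left out in turn. A voom fit with library quality weights was added after seeing the data. Leaving out mitochondrially encoded genes was planned and not run, as the files held none.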

Results

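Messenger RNA was sequenced from the left atria of adult mice in 10 libraries that fall into 4 groups by their labels. Vehicle-treated animals (CTL) and animals given ibrutinib (IBR), an inhibitor of Bruton's tyrosine kinase used against B cell cancers, gave 3 libraries each. Untreated wild-type animals (WT) and animals described as having a heart-specific knockout of Csk (KO) gave 2 libraries each. Csk encodes C-terminal Src kinase, which holds kinases of the Src family inactive. The series title names atrial fibrillation under ibrutinib, and the design implies a comparison of the drug with vehicle, a comparison of the genotypes, and a comparison of both effects with each other. The libraries held between 14907331 (KO26) and 19960947 (WT35) counts on genes, and 15364 genes had enough counts to be tested. The labels call the libraries replicates without saying that each came from a separate animal, so p-values measure only the spread between these libraries.

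The targeted gene did not follow the genotype labels. Csk (ENSMUSG00000032312) stood at 18.3 and 17.8 CPM (read counts scaled to a common library size) in WT35 and WT338 and at 24.7 and 35.5 CPM in KO26 and KO337, and in CTL and IBR it averaged 24.3 ± 0.557 and 23.9 ± 2.51 CPM (SD, n = 3 each). The log2 difference between the libraries labelled KO and WT was 0.74 with a standard error (SE) of 0.18, and its adjusted p of 0.0608 lay beyond the threshold. Without KO337 the difference was 0.44. Counts over a whole gene in whole tissue cannot resolve a deleted exon or a loss in heart muscle cells alone, so Csk neither checks nor excludes the knockout. The libraries are therefore called labelled KO, and each direction below rests on a label that the Csk counts neither bear out nor exclude.

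The libraries separated by experiment before they separated by group. The first principal component carried 60.8% of the variance and placed the CTL and IBR libraries between -61.6 and -26.5, WT at 34.7 and 42.9, KO26 at 70.6 and KO337 at 119.8. Both libraries labelled KO differed from each other more than any other pair within a group, with a Spearman correlation of 0.955 against 0.984 to 0.991 for the rest. The 10 most abundant genes took 7% of the counts in KO337, 10.8% in KO26 and 12.4% to 14.4% in the other libraries. No pair of libraries within a group agreed within sampling noise, so none was taken as a repeat deposit of another, which does not show that they came from separate animals. CTL and WT lie in different parts of the design and were not tested against each other.

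**Figure D1:**
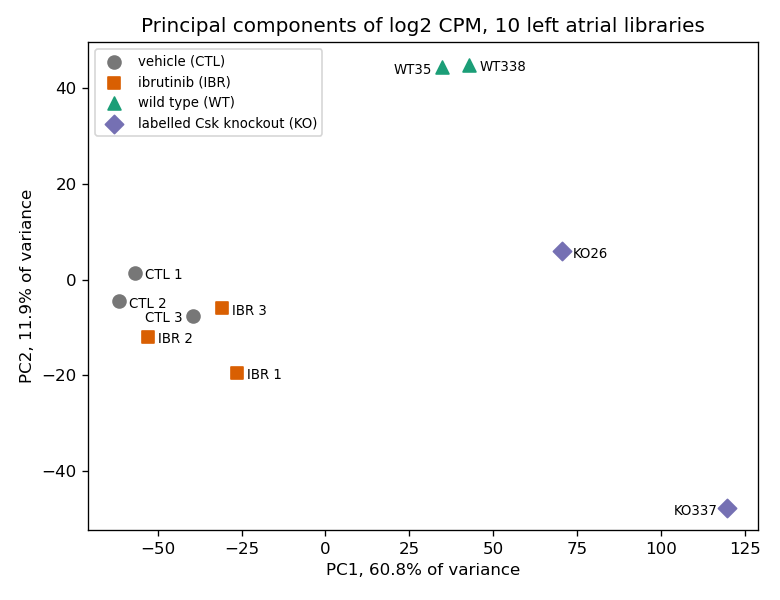
Principal components of log2 CPM over the 15364 tested genes, one point per library, coloured by group, with the share of variance on each axis. CTL and IBR libraries lie to the left, WT at 34.7 and 42.9 on the first component, and the libraries labelled KO, KO26 and KO337, at 70.6 and 119.8.

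Genes of immune cells were higher in the libraries labelled KO than in WT. H2-Eb1 (ENSMUSG00000060586), a chain of the MHC class II complex that presents antigen to T cells, was 34-fold higher, at 256 and 228 CPM against 7.72 and 6.48 CPM (log2 5.09, SE 0.55, adjusted p = 0.00994). Cd74, the class II invariant chain, was 14.4-fold higher and stood at 516 and 457 CPM in the libraries labelled KO, so the class II genes were about as high in KO26 as in KO337. Ptprc, the pan-leukocyte antigen CD45, was 6.24-fold higher at 49 and 121 CPM, and Adgre1, which encodes the macrophage antigen F4/80, was 4.31-fold higher at 54.2 and 110 CPM. Without KO337 the log2 difference of Ptprc was 1.83 rather than 2.64, and neither it nor Cd74 was called (adjusted p of 0.0544 and 0.0978). In all, 201 genes were higher and 138 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test, of 15364 tested, with 3947 at an unadjusted p under 0.05 against 768 by chance. The libraries of both groups did not overlap for 53.2% of genes, where chance gives 33.3%. As Csk itself was higher in the libraries labelled KO, these directions are those of the labels.

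Of the immune lists, those of antigen presentation, macrophages, T and NK cells, cytokines and interferon response were called higher, while neutrophil and mast cell markers (median 1.40, adjusted p = 0.0976) and B and plasma cell markers (median 0.97, adjusted p = 0.299) were not. Of 13 tested antigen presentation genes 6 were called higher, with a list median of 2.05 on the log2 scale, among them H2-Ab1 (15.8-fold). All 13 passed when adjusted over the list alone, and the list was called by the preset-correlation test (adjusted p = 2.99e-18) but not with an estimated correlation (adjusted p = 0.241). The macrophage and monocyte list had a median of 2.06 with 6 of 20 members called, including Ccr2, the receptor that draws monocytes into tissue, at 22.1 and 11.8 CPM against 1.58 and 0.629 CPM. Its call was lost with an estimated correlation (adjusted p = 0.268), and 15 members passed when adjusted over the list alone. T and NK cell markers had the largest median of the 38 lists, 2.73, with Ccl5 (18-fold), Cd3e (6.44-fold) and Thy1 (5.15-fold) among 4 of 13 members called. By fry 12 lists were called, with adjusted p of 0.00573 for this one and 0.0166 to 0.0411 for the others. Those were antigen presentation, macrophages, cell cycle, p53 targets, sarcomere, calcium handling, fatty acid oxidation, glycolysis, clock and both kinase lists. The T and NK list was the one whose call held with an estimated correlation (adjusted p = 0.046). When adjusted over the list alone, 12 of its members were higher and 1 lower. Their levels were low, as Cd3e reached 1.8 and 1.49 CPM. Thy1 (9.46 and 30.9 CPM) is also on the fibroblast list, and without KO337 it differed by 1.25 on the log2 scale and neither it nor Cd3e was called (adjusted p of 0.162 and 0.131). Among 29 cytokines and chemokines, Il1b (13.7-fold), Ccl8 (4.94-fold) and Ccl5 were called higher, while Ccl11, the eosinophil attractant eotaxin, was called 9.63-fold lower. The list had an adjusted p of 0.00807 with the preset correlation and 0.457 with an estimated correlation. Without KO337 the log2 difference of Il1b was 2.86 rather than 3.78, and neither it nor the list was called. All 25 tested interferon response genes had positive differences with a median of 1.01 and none was called singly. Ifit2 and Irf7 were the nearest, at log2 1.74 and 1.72 with adjusted p of 0.0511 and 0.0512, and the list's adjusted p was 5.71e-08 (adjusted p = 0.33 with an estimated correlation). Higher when adjusted over the list alone were 5 interferon response genes, and 6 cytokines and chemokines were higher and 1 lower.

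Other genes with the largest increases also included products of leukocytes. Cd72 (35.8-fold, SE 0.82 on the log2 scale), Dpep2 (22.4-fold), Ctss, which encodes the lysosomal protease cathepsin S (22.1-fold), Glipr1 (19.3-fold) and Havcr2 (18.1-fold) were higher in both libraries labelled KO. All 5 were lower in KO26 than in KO337, as Ctss was at 52.9 and 630 CPM, Dpep2 at 1.92 and 24 CPM, Glipr1 at 2.73 and 20.6 CPM, Havcr2 at 4.3 and 24.4 CPM and Cd72 at 5.8 and 21.8 CPM. Without KO337 their log2 differences were 1.75 for Ctss, which was still called, and 1.71, 2.15, 2.41 and 3.89 for Dpep2, Glipr1, Havcr2 and Cd72, which were not (adjusted p from 0.0699 to 0.217), and neither were Mmp3 (3.85) and Btk (1.26). Mmp3, which encodes the matrix-degrading enzyme stromelysin, was 30.3-fold higher at 14.5 and 45.5 CPM. Esr1, the oestrogen receptor alpha gene, was also 30.3-fold higher (log2 4.92, SE 0.56, adjusted p = 0.0104), at 98.9 and 234 CPM against 4.16 and 6.92 CPM in WT and at most 3.76 CPM in any CTL or IBR library. Of the 14 kinases that ibrutinib binds, 3 were called higher. Btk, its intended target, stood at 4.7 and 11.8 CPM against 2.37 and 1.45 CPM (4.29-fold, adjusted p = 0.0465). The list had a median of 0.51 (adjusted p = 0.00161, and adjusted p = 0.222 with an estimated correlation). In the list of Csk and Src family kinases, with a median of 0.78 over 13 members, 3 genes were called, among them Ptprc and Ptpn22, the last a phosphatase of lymphocytes that was 5.91-fold higher. The adjusted p of that list was 7.71e-07, and with an estimated correlation its adjusted p was 0.241. Of its members 9 were higher when adjusted over the list alone, and of the kinases bound by ibrutinib 6 were higher and 1 lower.

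Sarcomere, atrial muscle, ion channel and calcium handling lists were lower in the libraries labelled KO, and the ventricular muscle list was not called. Cacna1h, a T-type calcium channel, was 2.15-fold lower (log2 -1.11, adjusted p = 0.0465), at 110 and 63.3 CPM in the libraries labelled KO against 188 and 186 CPM in WT. Of the 32 ion channel and gap junction genes 2 were called lower, and the list had a median of -0.61 (adjusted p = 5.65e-05, and adjusted p = 0.321 with an estimated correlation). Kcna5 and Gja5 differed by -0.58 (SE 0.40) and -1.02 (SE 0.44) with adjusted p of 0.381 and 0.182. The calcium handling list had the same median of -0.61 with Ppp1r1a, an inhibitor of protein phosphatase 1, called 3.16-fold lower, while Casq2, calsequestrin of the sarcoplasmic reticulum, differed by -0.94 (adjusted p = 0.0601). The adjusted p of this list was 0.000298, and with an estimated correlation its adjusted p was 0.311. All 16 sarcomere genes had negative differences with a median of -0.81 (adjusted p = 2.98e-09, and adjusted p = 0.321 with an estimated correlation), and none was called singly, with Ldb3 at -0.98 and an adjusted p of 0.0622. Of the atrial muscle list, Stard10 stood at 370 and 160 CPM against 725 and 666 CPM (adjusted p = 0.0623), and the atrial myosin light chain Myl7 at 3230 and 2040 CPM against 4620 and 4960 CPM (adjusted p = 0.115). Its median was -0.80 (adjusted p = 5.65e-05, and adjusted p = 0.33 with an estimated correlation). Genes at loci associated with atrial fibrillation had a median of -0.36, and 1 member was called (adjusted p = 0.015, and adjusted p = 0.356 with an estimated correlation). Without KO337 neither this list nor the atrial muscle list was called, and both kept their direction. When adjusted over the list alone, 10 sarcomere genes, 7 atrial muscle genes, 5 ion channel genes, 3 calcium handling genes and 2 genes at the fibrillation loci were lower, and 1 member each of the last 3 lists was higher. The natriuretic peptide genes were not called, with Nppa at -0.08 (SE 0.24) and Nppb at -0.03 (SE 0.56).

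Lists of energy metabolism and the clock were called lower with the preset correlation and not with an estimated one, with 0 metabolic genes and 2 clock genes called singly. By fry the adjusted p was 0.0411 for fatty acid oxidation, for glycolysis and for the clock, and 0.0622 for oxidative phosphorylation. All 56 oxidative phosphorylation genes had negative differences with a median of -0.77, 48 of them past the threshold when adjusted over the list alone and none over all genes, and Ndufa9, a subunit of complex I, stood at -0.85 (adjusted p = 0.0708). The list's adjusted p was 3.55e-21, and with an estimated correlation its adjusted p was 0.321. Fatty acid oxidation genes had a median of -0.82 with 22 of 28 lower when adjusted over the list alone and Echs1 at -0.93 (adjusted p = 0.0778), and glycolysis genes had a median of -0.38 with Pfkm at -0.86 (adjusted p = 0.0654). Both lists were called (adjusted p of 2.23e-10 and 0.00124) and not with an estimated correlation (adjusted p of 0.311 and 0.321). In the circadian clock list, median -0.83, Hlf (3.59-fold) and Nr1d2, which encodes the repressor REV-ERB beta (2.09-fold), were called lower, and 14 of 16 members were not called (adjusted p = 0.000174, and adjusted p = 0.311 with an estimated correlation). Bag3, a co-chaperone of muscle, was 1.83-fold lower and headed the heat shock list, median -0.72 (adjusted p = 0.000694, and adjusted p = 0.321 with an estimated correlation). Lower when adjusted over the list alone were 5 glycolysis, 6 clock and 4 heat shock genes. Among the largest decreases outside the lists were Igfbpl1 (11.5-fold), Sh3gl2 (11.3-fold), Rps6ka6 (9.45-fold), Vsnl1 (7.88-fold) and Casc1 (6.77-fold). Rps13-ps1, a processed pseudogene of a ribosomal protein gene whose reads can be shared with other copies, was at 11 and 9.05 CPM in WT and at 0.174 and 0.362 CPM in the libraries labelled KO.

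The collagen genes Col1a1 and Col3a1 were high in KO337 and much less so in KO26. Of the 14 tested fibroblast markers, 11 had positive differences, and the order of KO26 and KO337 varied between members. Dpt stood at 304 CPM in KO26 and 709 CPM in KO337, Thy1 at 9.46 and 30.9 CPM and Tcf21 at 16.3 and 20.1 CPM. Pdgfra stood at 169 CPM in KO26 and 135 CPM in KO337, against 94.7 and 121 CPM in WT, and was not called. Col1a1 stood at 1670 CPM in KO337, 134 CPM in KO26 and 107 and 98.7 CPM in WT, and Col3a1 at 3670, 531, 402 and 314 CPM in the same order. Their log2 differences of 3.13 (SE 0.92) and 2.55 (SE 0.75) were not called, with adjusted p of 0.0896 and 0.0909, and neither were Postn, Acta2 or Lyz2 (adjusted p of 0.176, 0.418 and 0.058). The collagen and matrix list had a median of 1.64 with all 31 members positive and Mmp3 called, the activated fibroblast list 1.57 with Ltbp2 at 4.62 (adjusted p = 0.0593), the fibroblast list 0.48 with Thy1 called, and the smooth muscle and pericyte list 0.82 with Lmod1 at 3.56 (adjusted p = 0.0763). Their adjusted p were 7.75e-09, 9.05e-05, 0.0439 and 0.041, and with an estimated correlation each adjusted p lay between 0.395 and 0.586. Without KO337 all 4 of these lists lost their call, and so did the atrial muscle, fibrillation locus and cytokine lists. All of them kept their direction. Cell cycle genes had a median of 1.46 with Ube2c called at 2.32 and 4.12 CPM (adjusted p = 1.06e-08, and adjusted p = 0.321 with an estimated correlation), and p53 targets a median of 0.58 with Sesn2 called 2.11-fold higher (adjusted p = 0.0168, and adjusted p = 0.321 with an estimated correlation). When adjusted over the list alone, 14 collagen and matrix, 5 activated fibroblast, 3 fibroblast, 7 smooth muscle, 16 cell cycle and 6 p53 genes were higher and 1 smooth muscle gene lower. Endothelial markers had a median of 0 over 18 genes and were not called (adjusted p = 0.776). Median, mean and test differed in sign for the adipocyte list (median 0.48, mean 0.19, tested as lower), for the ventricular cardiomyocyte list (median -0.17, mean 0.12, tested as lower with an adjusted p of 0.868) and for the oxidative stress list (median -0.17, mean 0.04, tested as lower), which were not called. Of the lists not called, some had single members called. Tbx18 was called higher in the epicardial list, where it was the 1 positive member of 12 (median -0.59). Plin4, Kcna1, Srxn1 and Atp2a1 were called lower in the adipocyte, neural, oxidative stress and skeletal muscle lists.

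The number of genes called in the genotype comparison depended on the libraries and the tool. Leaving out one library gave, for genes higher and lower, 34 and 21 without KO337, 1830 and 2103 without KO26, 1 and 13 without WT35, 2 and 19 without WT338, 8 and 11 without IBR 3, 56 and 45 without CTL 1, 64 and 57 without CTL 2, 97 and 65 without CTL 3, 62 and 38 without IBR 1, and 98 and 60 without IBR 2. All 39 named genes called kept their sign without KO337. This was fixed beforehand, as KO26 lay beyond both WT libraries for each of them, so it does not test dependence on KO337. A fit of the 4 libraries alone called 0 genes (2115 at an unadjusted p under 0.05), and DESeq2 called 902 and 956.

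**Figure D2:**
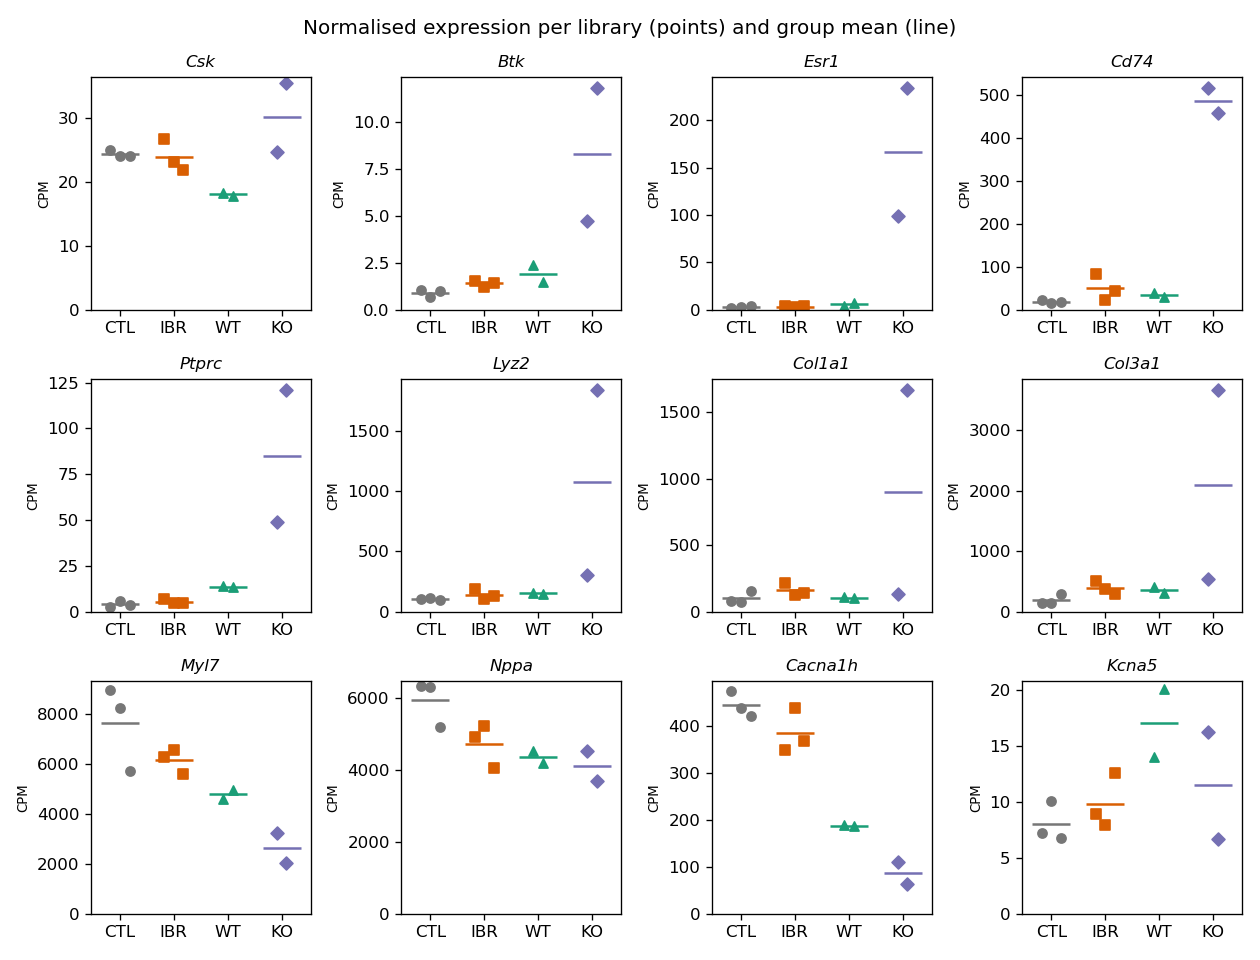
Normalised expression in CPM (vertical axes, linear from 0) of 12 genes in each library, with points for libraries and lines for group means in the groups CTL, IBR, WT and KO. Csk lies at 24.7 and 35.5 CPM in the libraries labelled KO and at 18.3 and 17.8 CPM in WT, and Col1a1 reaches 1670 CPM in KO337 against 134 CPM in KO26.

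Under ibrutinib, no single gene was called, and gene lists were called with a preset correlation but not with an estimated one. Interferon response genes were higher as a list (adjusted p = 8.79e-16, and adjusted p = 0.434 with an estimated correlation), with 23 of 25 members above vehicle and a median of 0.83 on the log2 scale. Bst2, an antiviral membrane protein, stood at 22.2 ± 4.83 CPM against 12.6 ± 1.84 CPM (SD, n = 3 each). Antigen presentation genes had a median of 0.81 with all 13 members positive (adjusted p = 3.45e-13, and adjusted p = 0.434 with an estimated correlation), and H2-Aa, a class II chain, stood at 50.7, 10.8 and 26.2 CPM in IBR 1, 2 and 3 against 8.03 to 10.2 CPM in CTL. All 56 oxidative phosphorylation genes lay below vehicle with a median of -0.33. With edgeR's quasi-likelihood test no gene passed an adjusted p of 0.05. The smallest adjusted p was 0.823, with 848 genes at an unadjusted p under 0.05 against 768 by chance, while limma-voom called 0 genes and DESeq2 called 2, Myl9 and Gm10222, both lower. The count of 848 was 499, 391 and 1668 without CTL 1, 2 and 3, 456 and 475 without IBR 1 and 3, 1512 without KO26 and 1453 without KO337, and 1550 for one of the other splits of the 6 libraries. The libraries of both groups did not overlap for 13.5% of genes, where chance gives 10%.

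By the preset-correlation test 13 of 38 lists were called, 8 higher and 5 lower, and with an estimated correlation none was, the smallest adjusted p being 0.434. Of the 10 splits of the 6 libraries into groups of 3, 4 called at least as many lists, the real one included. When adjusted over the list alone, 5 of the 13 antigen presentation genes passed, among the leading members H2-Aa (log2 1.71, SE 0.45) and H2-DMb1 (1.98, SE 0.56). Both were highest in IBR 1, with H2-DMb1 at 7.22, 1.9 and 2.32 CPM in IBR 1, 2 and 3 against 0.432 to 1.31 CPM in CTL. Connective tissue lists were called higher as well. Epicardial and mesothelial markers had a median of 0.71 with all 12 positive, led by Efemp1 at 81.4 ± 14.5 against 42.0 ± 12.2 CPM, fibroblast markers a median of 0.63 with all 14 positive, led by Pdgfra at 75.3 ± 13.2 against 42.1 ± 14.1 CPM, and collagen and matrix genes a median of 0.61 with 30 of 31 positive, led by Dcn at 0.78 (SE 0.26). Their adjusted p were 4.82e-12, 1.59e-10 and 3.1e-09, and with an estimated correlation the adjusted p were 0.434, 0.434 and 0.553. Macrophage markers had a median of 0.46 with 18 of 20 positive, led by Mrc1, the mannose receptor of resident macrophages, at 63.3 ± 2.77 against 42.6 ± 7.34 CPM. Endothelial markers followed with a median of 0.30, led by Tek, and cell cycle genes with a median of 0.55, led by Top2a at 1.7 ± 0.818 against 0.671 ± 0.285 CPM. Their adjusted p were 1.44e-07, 0.000141 and 0.000141, and with an estimated correlation the adjusted p were 0.434, 0.457 and 0.533. Markers of endothelium, fibroblasts, epicardium and macrophages were thus above vehicle together. When adjusted over the list alone, 3 fibroblast genes passed, 1 each of the interferon, epicardial and macrophage lists, and 0 of the collagen, endothelial and cell cycle lists.

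Of the 5 lists called lower, those of sarcomere genes and of the hypertrophic programme hold heart muscle genes. The atrial cardiomyocyte list was not called by the preset-correlation test (median -0.14, 2 of 14 positive, adjusted p = 0.0814). The oxidative phosphorylation list had an adjusted p of 1.64e-12 (adjusted p = 0.575 with an estimated correlation), with Atp5l, a subunit of ATP synthase, at 155 ± 7.7 against 215 ± 44 CPM. Glycolysis genes had a median of -0.20 with none of 20 positive, led by Pgam1, and immediate early genes a median of -0.39 with none of 18 positive, led by Nr4a2 and with Fosb at 11.7 ± 6.41 against 30.3 ± 16.2 CPM. Both had adjusted p between 0.000131 and 0.000141, and both an adjusted p of 0.457 with an estimated correlation. The hypertrophic gene programme had a median of -0.33 (adjusted p = 0.0163, and adjusted p = 0.457 with an estimated correlation) with Nppb, which encodes B-type natriuretic peptide, at 264 ± 74.6 against 606 ± 412 CPM. The vehicle mean of Nppb rests largely on CTL 2, at 1080 CPM against 418 and 322 CPM in CTL 1 and 3. In IBR it was at 202 to 346 CPM. Sarcomere genes had a median of -0.17 (adjusted p = 0.0428, and adjusted p = 0.741 with an estimated correlation) with cardiac actin, Actc1, at 8010 ± 394 against 11900 ± 1350 CPM. No member of these lists passed when adjusted over the list alone, as over all genes. Median, mean and test differed in sign for 3 lists that were not called, namely the neutrophil and mast cell list (median -0.37, mean -0.56, tested as higher), the ventricular list (median -0.26, mean 0.01, tested as lower) and the atrial fibrillation loci (median -0.03, mean 0.01, tested as higher). Lists of calcium handling, ion channels, circadian clock, kinases bound by ibrutinib and the Csk and Src family were not called, with medians between -0.11 and 0.09.

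Single genes with the smallest p among those whose libraries did not overlap are given as values, since none passed the adjustment. Myl9, the regulatory light chain of smooth muscle and non-muscle myosin, was at 94.6 ± 1.86 CPM under ibrutinib against 180 ± 37.0 CPM (log2 -0.93, SE 0.15, unadjusted p = 8.21e-05 in edgeR's model over all genes). Phlda1 (-0.82), Dffb (-0.98), Msrb1 (-0.55), Vegfa (-0.53), Sh3bgr (-0.50), Tomm40 (-0.46) and Dazap1 (-0.43) were the other genes below vehicle. Above vehicle were Lrrc17 (1.35), Frk (1.17), a kinase related to Src, Efemp1 (0.95), Pdgfd (0.87), Itpripl1 (0.86), Hpgd (0.85), Bst2 (0.82) and Mrc1 (0.57). Csk differed by -0.03 (SE 0.15) and Btk by 0.64 (SE 0.42) at about 1 CPM. Of the other genes chosen in advance, Nppa stood at -0.33 (SE 0.19), Myl7 at -0.31 (SE 0.24), Gja5 at -0.09 (SE 0.36), Kcna5 at 0.29 (SE 0.33), Acta2 at -0.43 (SE 0.48), Il6 at -1.77 (SE 1.20), Col1a1 at 0.63 (SE 0.69), Col3a1 at 0.97 (SE 0.59), Postn at 0.85 (SE 0.54), Lyz2 at 0.42 (SE 0.50) and the ventricular light chain Myl2, at trace level, at 1.86 (SE 0.71), each with an adjusted p of 0.823 or more.

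**Figure D3:**
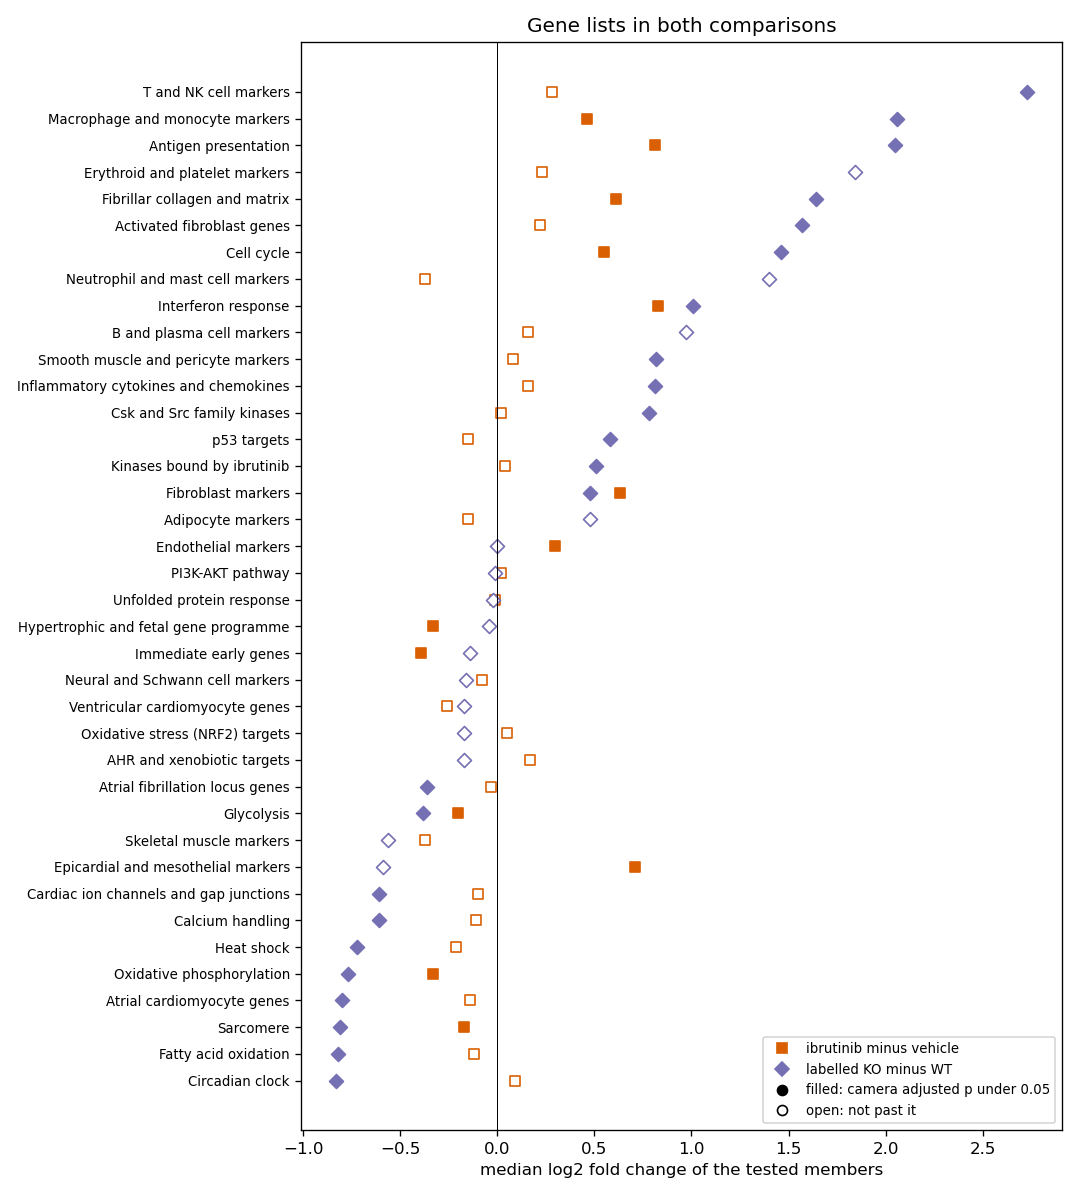
Median log2 fold change of the tested members of each of 38 gene lists (horizontal axis), squares for ibrutinib minus vehicle and diamonds for the libraries labelled KO minus WT, filled where the preset-correlation test gave an adjusted p under 0.05. T and NK cell markers lie at 2.73 in the genotype comparison, and the interferon response list at 0.83 and 1.01.

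The effects of ibrutinib and of the labelled genotype differed for 4 genes, each with an adjusted p of 0.0494 in edgeR's test of the difference. Among them Ccl11, Ccl24, the eosinophil attractant eotaxin-2, and Lgr6, a receptor for R-spondins, were lower in the libraries labelled KO and not under ibrutinib. Lgr6 stood at 62.1 and 59 CPM in the libraries labelled KO, at 204 and 190 CPM in WT, and at 161 to 210 CPM in CTL and IBR, a difference of effects of 1.58 (SE 0.20) on the log2 scale. For Ccl11 and Ccl24 the differences were 3.86 (SE 0.49) and 2.57 (SE 0.33). The next genes by the rule were not called, among them Rps13-ps1 at 4.46, Esr1 at -4.48, H2-Eb1 at -3.75, Lrmp at -2.48, Sesn2 at -1.59 and Myl9 at -1.46, with adjusted p from 0.0597 to 0.248. Myl9 stood at 248 and 282 CPM in the libraries labelled KO and at 184 and 182 CPM in WT (log2 0.53, adjusted p = 0.114), against the lower values under ibrutinib. By the preset-correlation test 21 of 38 lists differed, 11 higher and 10 lower, and with an estimated correlation 0 did (smallest adjusted p = 0.101). The count of 4 genes was 0 with limma-voom and 143 with DESeq2. It was 1564 without KO26, with all 4 among them, 2 without IBR 2 and 1 without CTL 2, with 1 of the 4 in each case, 3 without IBR 1 and without KO337 and 1 without WT35, with 0 of the 4 among them, and 0 without CTL 1, CTL 3, IBR 3 or WT338.

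Across the 15364 genes, both effects were positively correlated, with a Pearson r of 0.295 and a Spearman rho of 0.378. Genes are not independent replicates, so the p came from relabelling libraries within each experiment: the exact permutation p was 0.0667 over 120 assignments, 2-sided, where the smallest possible is 0.0333, and the largest r in size among the other assignments was 0.327. The comparisons share no control libraries. Of the 339 genes called in the genotype comparison, 272 (80.2%) had the same sign under ibrutinib, with an r of 0.485 over these genes. These signs rest on labels that Csk neither bears out nor excludes. With WT and KO exchanged, the genotype differences change sign, so r was -0.295, rho -0.378 and r over the called genes -0.485, with 66 (19.5%) of the same sign. These mirrored values do not test the labels. Without IBR 1 the r was 0.142, without WT338 0.186, without KO337 0.25 (exact permutation p = 0.0333, the smallest possible), and without any filter on low counts 0.062.

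**Figure D4:**
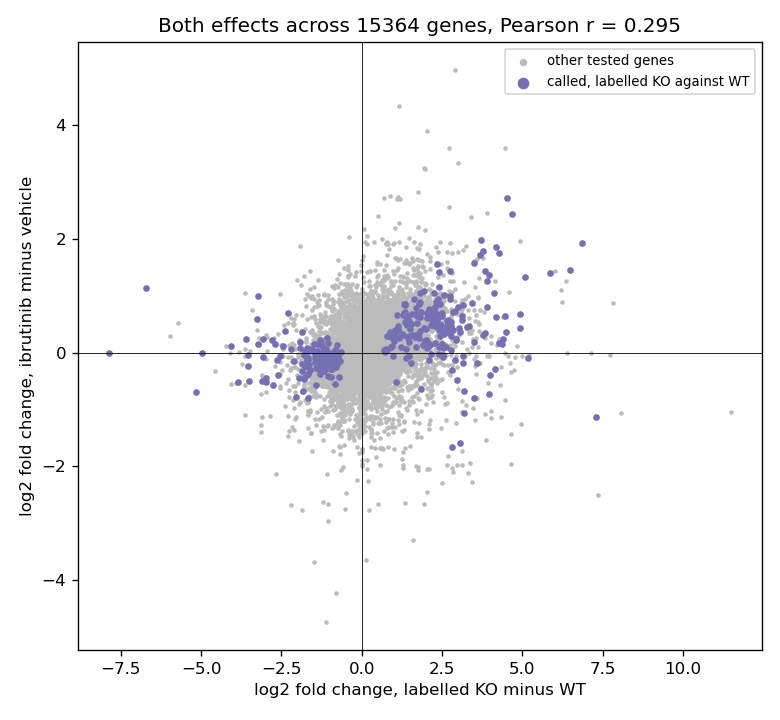
Log2 fold change of each of 15364 genes for the libraries labelled KO minus WT (horizontal axis) and for ibrutinib minus vehicle (vertical axis), with the 339 genes called in the genotype comparison coloured. Pearson r over all points is 0.295, and 272 of the called genes have the same sign on both axes. Under ibrutinib the called genes have medians of 0.46 (higher) and -0.13 (lower).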

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

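The test of the difference between effects was planned. Of the 4 genes that differed, 3 are given here. Each stands here because its response to ibrutinib differed from its difference between the libraries labelled KO and WT, by edgeR's test of that difference with an adjusted p of 0.0494. For Ccl11 the ibrutinib effect lay above the labelled knockout effect by 3.86 on the log2 scale (SE 0.49), with 13.2 and 16.2 CPM in WT and 1.74 and 1.31 CPM in the libraries labelled KO. For Ccl24 it was 2.57 (SE 0.33), with 9.7 and 11 CPM in WT, 1.92 and 1.86 CPM in the libraries labelled KO and 2.9 to 3.74 CPM in CTL and IBR. For Lgr6 it was 1.58 (SE 0.20), with 204 and 190 CPM in WT and 62.1 and 59 CPM in the libraries labelled KO. The count of 4 was 0 with limma-voom, with upper-quartile factors and with genes of a mean of at least 5 CPM, 84 without a filter and 143 with DESeq2, and the libraries labelled KO had more Csk than WT, so the direction is that of the labels. No group had 4 or more libraries, so single libraries were not tested against their group.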

How the results depend on the processing

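The fit with library quality weights was chosen after seeing the data, and all other settings before. For ibrutinib, 0 genes were called higher under every setting, and 0 lower except 2 without a filter on low counts and 2 with DESeq2, in both cases Myl9 and Gm10222. Its genes at an unadjusted p under 0.05 ran from 391 to 1668 without one library and were 2471 with quality weights. Its 13 called lists were 11 to 18 under every other scaling, filter, threshold, fit and left-out library (13 to 18 for libraries left out) and 0 with an estimated correlation and 0 by fry. The 23 lists of the genotype comparison were 19 to 25 under other scalings, filters, thresholds and fits, 17 to 24 with a library left out, 1 with an estimated correlation and 12 by fry.

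In the libraries labelled KO, Csk was higher but not called. There, the 201 genes higher and 138 lower became 821 and 740 at a threshold of 0.1, and 1 and 7 at 0.01. They were 467 and 679 without a filter, and 38 and 39 with a mean of at least 5 CPM, where fewer genes are tested. DESeq2 gave 902 and 956, and quality weights gave 108 and 16. With only the 4 libraries of the comparison, where 2 residual degrees of freedom are left, the counts were 0 and 0. Upper-quartile factors gave 89 lower. Without one library the counts ran from 1 to 1830 higher and from 11 to 2103 lower, the highest without KO26, where KO337 alone is assumed to vary like the other groups. Without KO337, 18 of the 34 higher and 20 of the 21 lower were shared with the genes called from all libraries. The 4 genes that differed between effects became 8 at 0.1, 0 at 0.01, 84 without a filter, 143 with DESeq2, 0 with upper-quartile factors, with at least 5 CPM, with limma-voom and with quality weights, and 0 to 1564 without one library, where the genes called without IBR 1, WT35 or KO337 include 0 of the 4. The correlation of 0.295 was 0.378 as Spearman's rho, 0.485 over called genes, 0.395 with only the libraries of each comparison, and 0.142 to 0.338 without one library; its exact permutation p passed 0.05 only without KO337 (0.25, p = 0.0333, the smallest possible). The cause of these moves was not tested beyond the number of genes or libraries.

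Labels gave CTL and IBR the same numbers, but same-numbered libraries deviated together with correlations of 0.016, 0.162 and 0.032, so the numbers were not taken as pairs, and IBR 1 correlated best with CTL 3 (0.182). With the replicate block, ibrutinib had 0 genes and 12 lists, the genotype comparison 7 genes higher and 10 lower and 24 lists, the difference 0 genes and the correlation was 0.301.

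Signs turned for uncalled genes, of which Il6 and Acta2 in the libraries labelled KO were not near 0, at -0.68 (SE 1.27) and 0.77 (SE 0.56) with all libraries. Under ibrutinib Csk became 0.0171 without a filter and 0.000472 with only the libraries of the comparison, and ran from -0.114 to 0.0327 with a library left out. Gja5 ran from -0.449 to 0.185, and was 0.0792 without CTL 1. In the libraries labelled KO, Nppb became 0.0158 with at least 5 CPM, 0.107 with limma-voom, 0.0889 with quality weights, 0.0221 without KO337 and -0.512 to 0.676 over all left-out libraries, and Il6 0.231 with limma-voom, 0.246 with quality weights, 0.0981 without KO26 and -2.64 to 2.64 over all left-out libraries. Acta2 ran from -0.197 (without KO337) to 1.48, and Nppa from -0.256 to 0.039 (without KO337). Depth limits genes of a few CPM, and scaling moved the median of all genes by under 0.1.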

Other observations

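Tests on Csk, Esr1, cell type lists, pseudogenes and the genes called in the libraries labelled KO were chosen after these results were seen, and so were their bounds; the splits of the CTL and IBR libraries were planned. MHC class II and leukocyte genes did not keep one ratio between both libraries labelled KO. H2-Eb1 was at 256 CPM in KO26 and 228 CPM in KO337, and Cd74 at 516 and 457 CPM, while Ptprc was at 49 and 121 CPM, Ctss at 52.9 and 630 CPM and Lyz2 at 307 and 1840 CPM. Ccr2 and Ccl5 lay the other way, at 22.1 and 7.6 CPM in KO26 and 11.8 and 2.72 CPM in KO337. Under ibrutinib the class II genes varied in parallel between libraries, as H2-Aa, Cd74 and H2-Ab1 were at 50.7, 83 and 33.1 CPM in IBR 1 and at 10.8, 21.2 and 8.44 CPM in IBR 2. Ighm, the antibody heavy chain mu, varied within genotype groups, at 10.1 and 53.1 CPM in WT35 and WT338 and 17.4 and 47.1 CPM in KO26 and KO337. Between the experiments, which no comparison joins, Atp5l stood at 215 ± 44 CPM in CTL and 20.8 ± 4.56 CPM in WT (SD, n = 3 and 2).

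For ibrutinib, the real split of the CTL and IBR libraries called 0 genes and 10 of the 10 splits of these 6 libraries called as many, the highest other being 0. It called 13 lists, and 4 of the 10 splits called as many, the highest other calling 18. With 10 splits a share under 0.05 cannot be reached.

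Csk and Esr1 were both higher in the libraries labelled KO. For Esr1, leukocytes that bring it along with Ptprc cannot be told apart: the Esr1 rise per unit of Ptprc rise (2.63 in KO26 and 2.14 in KO337) was at least 4.16 times the highest Esr1 to Ptprc ratio in WT, but 2.04 times that of CTL 3 (1.05), less than the spread of this ratio over the other 8 libraries (3.48-fold). For Csk, a larger share of leukocytes cannot be told apart from a change in other cells: the Csk rise per Ptprc rise was 0.189 and 0.164, a ratio of 1.16 between both libraries, but that bound was set with the values in view. An exchange of all WT and KO labels cannot be told apart either, as Csk in WT was 0.747 of its mean in CTL and IBR, which belong to another experiment, and counts per gene do not show a deleted part. A hypothesis left untested is that reads of a recombinase fused to an oestrogen receptor domain may be counted as Esr1, which exon-level reads would decide, while the labels name no such transgene and a biological change in Esr1 stays open.

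Antigen presentation, macrophage, and T and NK lists were higher and sarcomere and atrial muscle lists lower in the libraries labelled KO, of which the T and NK call held with an estimated correlation (adjusted p = 0.046), while the neutrophil, B cell and ventricular lists were not called. A lower share of heart muscle cells alone would raise the lists of other cell types alike. Medians were 2.73 for T and NK markers (12 of 13 positive), 2.06 for macrophages (17 of 20) and 0 for endothelium (9 of 18). These values argue against that share alone for these lists. The T and NK and endothelial medians lay 2.72 apart on the log2 scale (permutation p = 1e-05 over 100000 permutations of 13 and 18 genes, the smallest they can give). Both lists were picked after their medians were seen and genes are not independent replicates, so this p adds no weight. KO337 alone cannot be told apart for the lists. Without it all 23 called lists kept their direction. With the preset correlation some, such as the atrial muscle list, lost their call, and others, such as the antigen presentation and the T and NK lists, kept it. That comparison rests on KO26 alone, which is then assumed to vary like the other groups. The bound of 2 in 3 lists keeping their call was set after the count was known. With an estimated correlation 1 list was called even with all libraries, so its loss says little. For H2-Eb1, Cd74 and H2-Ab1, KO337 alone is argued against. These genes were at 256, 516 and 178 CPM in KO26 and at most 7.72, 37.7 and 12.1 CPM in WT. Col1a1 went the other way, at 134 CPM in KO26, 1670 CPM in KO337 and 107 and 98.7 CPM in WT. Lymphoid tissue taken with the atrium cannot be told apart. A first test on the B cell list (median 0.97 against 2.73 for T and NK markers, adjusted p = 0.299 by camera) was replaced, after it was seen, by Cd79a. The Cd79a rise was at most 0.0058 of the Ptprc rise. At 0.58 and 0.86 CPM, against up to 0.793 CPM in CTL 2, Cd79a gave no sign of B cells rising with Ptprc. This is 1 gene chosen after the first result, and 7 of 9 tested B cell markers were positive, so lymphoid tissue is not excluded. Both more leukocytes in the atrium under the labelled genotype and a change in the leukocytes themselves stay open and untested, which cell counts by staining or sorting would decide.

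Some pseudogenes were present in 1 genotype group, such as Rps15a-ps8 at 1.78 and 1.57 CPM in WT and 0 in the other 8 libraries, and these genes were picked after their values were seen. A change in the parent gene is argued against for Rps13-ps1, which fell by 5.15 on the log2 scale while Rps13 differed by 0.17 (SE 0.20). A DNA variant between the animals, such as strain background, may account for them but cannot be told apart, because 3 gaps between the WT and KO libraries were looked at and the excess of pseudogenes depended on the gap: 17 of 488 genes at least 2-fold apart (after adding 0.2 CPM), 6 of 66 at 4-fold and 4 of 13 at 8-fold were pseudogenes, against 3.09% of all tested (Fisher's exact test, 1-sided, p = 0.339, 0.016 and 0.000513, adjusted over the 3 gaps 0.339, 0.024 and 0.00154). Gm6166, at 10.4 and 16.2 CPM in the libraries labelled KO and 0.346 and 0.943 CPM in WT, lies 8 tested genes from Csk, and DNA flanking the targeted gene is a candidate explanation that no fair test bears on, since the window of 20 neighbours was chosen when this closeness was known (exact hypergeometric p = 0.0173). Part of the genotype comparison could then follow the line of the animals and not Csk, which stays open.

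A further hypothesis was that genes called in the libraries labelled KO move the same way under ibrutinib. Their mean log2 change, signed by the genotype difference, was 0.281, the highest of the 20 assignments of the 6 libraries, of which the next was 0.272 (exact permutation, 1-sided, p = 0.05, the smallest possible), so the design cannot pass the threshold. With the labels WT and KO exchanged the mean only changes sign, to -0.281, the lowest of the assignments, which does not test the labels. The 201 genes that were higher had a median of 0.46 under ibrutinib and the 138 lower genes a median of -0.13. Their adjusted p were 3.39e-21 and 0.00105 by camera with the preset correlation, 0.18 and 0.41 with an estimated correlation, and 0.198 and 0.307 by fry.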
